A study of Mus musculus with 4 samples.

How the data were processed

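Whole-genome bisulfite libraries were made from sorted hair matrix keratinocytes of mice at postnatal day 4.5, with 2 WT and 2 Tet2/Tet3 DKO libraries (Krt14-Cre), grouped by the genotype and title in the labels. The labels do not say whether the libraries of a group came from separate animals, nor the sex of the animals. Reads were trimmed with Trim Galore and aligned with Bismark to GRCm38 (mm10), per the submitters' processing notes. The tool that called the regions, its smoothing, its bounds and its filters are not given in the sources used here. The values used were 1 table of the authors' own comparison, with 484555 regions.

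Per the file headers, each region in the deposited table has a mean methylation level for each of 2 groups, given as a fraction between 0 and 1, and these were multiplied to percentages here. Per the file headers, the table also gives a statistic for each region, summed over its positions and as its extreme value, which is treated here as a score with no fixed range, and the spread estimate that goes into it. The deposited table has no p-value, no read counts and no values per library, so the depth behind a level is unknown, no interval of a level could be given, and the planned tests on reads per library were not run. All listed regions were therefore counted as called, as fixed in advance for a table without p-values. The header does not name the groups. The WT was taken as group 1 from the order of the genotypes in the table's title, and not from the values, so that the direction of every difference rests on that order.

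No extreme statistic lay between -4.02 and 1.53, so the table holds regions past a bound for each sign, with the bound for a negative statistic (DKO higher) farther from 0. The mean statistic per position differed from the ratio of the mean difference to the spread estimate by an offset with a median of 1.57. The number of positions in a region counts the strands of a CpG mostly apart, since 89.2% of the regions of 2 positions were 2 bp wide, so 10 positions are about 5 CpGs. Differences are DKO minus WT in percentage points.

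Gene positions came from a RefSeq gene table of the same assembly (GRCm38), which gives gene start and end but no strand and no exons. Planned classes by promoter, exon and intron were replaced by 3 classes, within 1 kb of either gene end, inside a gene and between genes, for protein-coding genes. The planned upstream flank was replaced by 5 kb on either side, and promoters by either gene end with 1 kb on each side. The 28 gene lists were fixed before the data were examined and cover keratins, hair shaft and cornification genes, hair matrix and stem cell genes, signalling pathways, cell cycle, chromatin and DNA methylation genes, Hox and other developmental factors, imprinted and germline genes, protocadherins, olfactory receptors, housekeeping genes and markers of fibroblasts, melanocytes, immune cells, endothelium and muscle.

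For each list, the members with a region higher (or lower) in the DKO were counted and compared with 10000 random lists of the same size, matched on the decile of gene length as planned for a table of called regions only, with a two-sided permutation p and Benjamini-Hochberg adjustment over the 28 lists at 0.05. The smallest p that 10000 lists can give is 0.0002. Because most genes hold a listed region, a second measure was added after the data were seen, the percent of the gene window covered by regions at least 20 points higher in the DKO, averaged over the list and compared with 10000 circular shifts of the values along the genes in genome order, which keeps neighbouring genes together. Genes named in the text follow a rule fixed in advance. It takes the 6 genes with the largest gain and the 6 with the largest loss among regions of at least 10 positions that overlap a gene, the 2 members of each list with the largest difference where no p-value is given, and Tet1, Tet2, Tet3 and Krt14. Genes named for their window coverage were chosen after their values were seen, and some genes that these choices would name are not reported here.

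Both list tests were tested on simulated data over 21911 genes with 20 changed and 80 unchanged lists of 30 genes. The count test found 20 of 20 lists whose genes had an added 80% chance of a call, and called 3 of 80 unchanged lists (3.75%) at an unadjusted p under 0.05. The coverage test found 19 of 20 lists whose values were multiplied by 3, and called 7 of 80 unchanged lists (8.75%). Smaller effects were not simulated, and most coverage differences reported below are smaller than a factor of 3. Alternatives were a minimum difference, minimum numbers of positions, minimum length, merging of neighbours within 500 bp, autosomes only, other windows, and other nulls. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.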

Results

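DNA methylation was measured by whole-genome bisulfite sequencing in hair matrix keratinocytes, the proliferating epithelial cells at the base of the hair follicle that give rise to the hair shaft and its inner sheath. The cells came from mice at postnatal day 4.5. There were 2 WT libraries and 2 libraries from mice lacking Tet2 and Tet3 in Krt14-expressing epithelium (Tet2/Tet3 double knockout, DKO). TET enzymes oxidise 5-methylcytosine, a step towards its removal, and the comparison asks how cytosine methylation of these cells differs without Tet2 and Tet3. Bisulfite sequencing reads 5-methylcytosine and 5-hydroxymethylcytosine alike, so each level below is the sum of both. The values are group means for 484555 regions that the authors' deposited table lists for this comparison. Values per library were not used here and the depth is unknown, so no difference below has a replicate check. The spread estimate given beside a region is the authors' own. Neighbouring regions can share its value, as several near Tet2 do at 3.60 points, so it need not be measured on that region alone. The WT was read as the table's first group from the order of names in its title, and every direction would turn if the order were the opposite.

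Large differences in methylation were almost all gains in the DKO. Of the 111462 regions whose levels differed by at least 20 percentage points, 111028 were higher in the DKO and 434 were lower, which is 99.61% higher (95% Wilson interval 99.57 to 99.65, counting error over regions only). The regions that gained at least 20 points had a median level of 45.6% in the WT (interquartile range 35.2 to 54.4) and 76.3% in the DKO (67.8 to 82.8). Together they covered 48.5 Mb, with a median length of 345 bp and a median of 11 cytosine positions. Over all listed regions, 233360 (48.2%) were higher in the DKO and 251195 were lower, and most listed regions differed by less than 10 points. With a minimum difference of 10 points, 91.1% of 138508 regions were higher. The table holds regions past a bound on the authors' statistic. This bound lay nearer to 0 for a positive statistic (WT mean higher in most regions) than for a negative one (DKO mean higher in all). Of the regions with a positive statistic, 110784 still had a higher DKO mean. The count over all listed regions therefore gives no genome-wide balance of gains and losses.

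**Figure D1:**
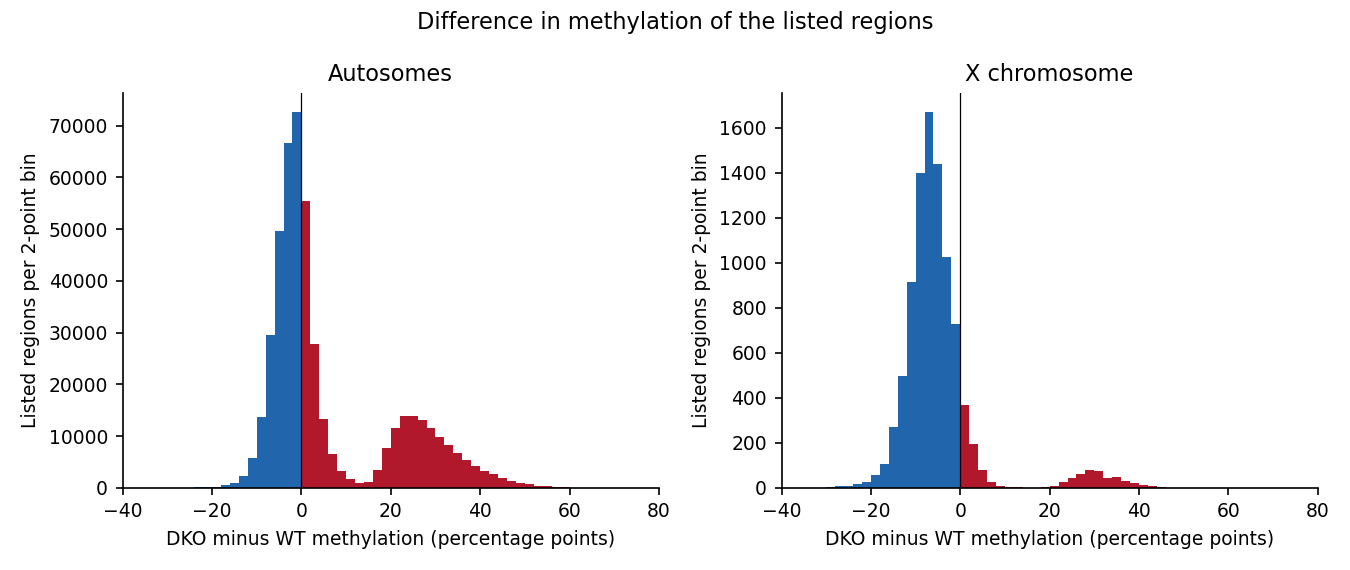
Number of listed regions (vertical axis) per 2-point bin of the difference in methylation, DKO minus WT, in percentage points (horizontal axis), for autosomes and the X chromosome, with gains in red and losses in blue. Autosomal listed regions form a group of small differences around 0 and a group of gains that rises from about 14 points. Regions between the bounds on the authors' statistic are not listed, so the gap between these groups does not show separate populations. On the X, 1909 of the 2372 regions that differ by at least 10 points, but 66 of those that differ by at least 20, are losses.

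Regions of intermediate methylation in the WT held most of the gains. Of the regions that rose by at least 20 points, 84.4% had a WT level between 20% and 60%, and 88.5% reached at least 60% in the DKO. Among the listed regions with a WT level of 20% to 40%, 85.0% rose by at least 20 points. As regions were listed for their difference, these shares do not describe all regions of such a level. The share was 76.0% at WT levels of 40% to 60% and 9.34% at 60% to 80%, and a rise of this size was not possible above 80%. Dense, CpG-island-like regions of the autosomes stayed low in both genotypes, with medians of 3.09% in the WT and 3.24% in the DKO over 6430 regions. The places of gains and losses were not compared by a test. Of the regions that gained at least 20 points, 51.4% lay inside a protein-coding gene, 5.37% within 1 kb of a gene end and 43.3% between genes, against 44.5%, 4.92% and 50.5% of all listed regions. Of the 12321 regions that lost at least 10 points, 75.7% lay between genes. The median difference over all listed regions was 0.702 points inside genes (interquartile range -2.48 to 21.1) and -1.30 points between genes (-4.76 to 5.05).

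Keratin genes of the inner root sheath and of the basal epidermis lay in windows where gains were dense. On average, regions that rose by at least 20 points covered 14.7% of the windows of the 9 inner root sheath and companion layer keratins (each gene with 5 kb on either side), against a mean of 2.67% over 21911 genes. This measure was added after the data were seen, and the value was the highest of the 28 gene lists (95% range of shifted lists 0.0151 to 6.37, circular-shift permutation test, adjusted p = 0.0008, the smallest this test can give here). All 9 members held such regions, covering 27.4% of the window of Krt25, 22.7% of Krt27 and 22.3% of Krt72. The 14 basal and interfollicular epidermal keratins followed with a mean of 10.4% (permutation test, adjusted p = 0.0008), led by Krt17 at 29.6% and Krt14 at 28.9%. The region of Krt28 at chromosome 11, 99373727 to 99375814, across a gene end, was at 24.5% in the WT and 82.5% in the DKO per the authors' deposited table (difference 58.0 points, spread estimate 3.22). That of Krt27 at 99345972 to 99346856, inside its gene, was at 18.6% and 71.5% in the authors' deposited table (52.9 points, spread estimate 3.62). A region 194 bp from Krt17, at 100254845 to 100256021, was at 26.5% in the WT and 83.3% in the DKO by the authors' deposited table (56.8 points, spread estimate 3.72).

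The 15 measured keratins of the hair cortex and cuticle had a mean coverage of 5.10% that did not pass the permutation test (adjusted p = 0.188) and passed only as a percent of cytosine positions (adjusted p = 0.0295). A region that rose by at least 20 points lay in the windows of 11 of the 15. Krt39 and Krt33a held the widest differences, from 32.8% to 86.0% at chromosome 11, 99516372 to 99517409, inside Krt39, and from 44.40% to 90.002% at 100008163 to 100008615, 2584 bp outside Krt33a, in the authors' deposited table. Keratins of simple epithelia and other tissues had a mean of 6.15% (permutation test, adjusted p = 0.0728, with 0.0258 as a percent of positions and 0.0420 against length-matched lists). Keratin-associated proteins, the matrix proteins between hair keratin filaments, had a mean of 3.54% and a median of 0% over 56 genes (permutation test, adjusted p = 0.440, with 0.0469 as a percent of positions, 0.0134 for gene bodies and 0.00280 against length-matched lists). The largest gains overlapped Krtap11-1 (29.4% in the WT, 84.5% in the DKO) and Krtap4-7 (24.6% and 76.0%) in the authors' deposited table. Genes of hair shaft structure and crosslinking, which include desmosomal proteins and transglutaminases, had a mean of 6.79% over 23 genes (permutation test, adjusted p = 0.0035, and 0.0818 for gene bodies), with Tgm1 at 14.0% of its window and Pkp1 at 14.0%. Inside the desmoplakin gene Dsp, at chromosome 13, 38164394 to 38165317, the level was 32.7% in the WT and 89.2% in the DKO per the authors' deposited table. The 24 genes of epidermal cornification had a mean of 1.69%, and 13 of them had no region that rose by 20 points (permutation test, adjusted p = 0.553).

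**Figure D2:**
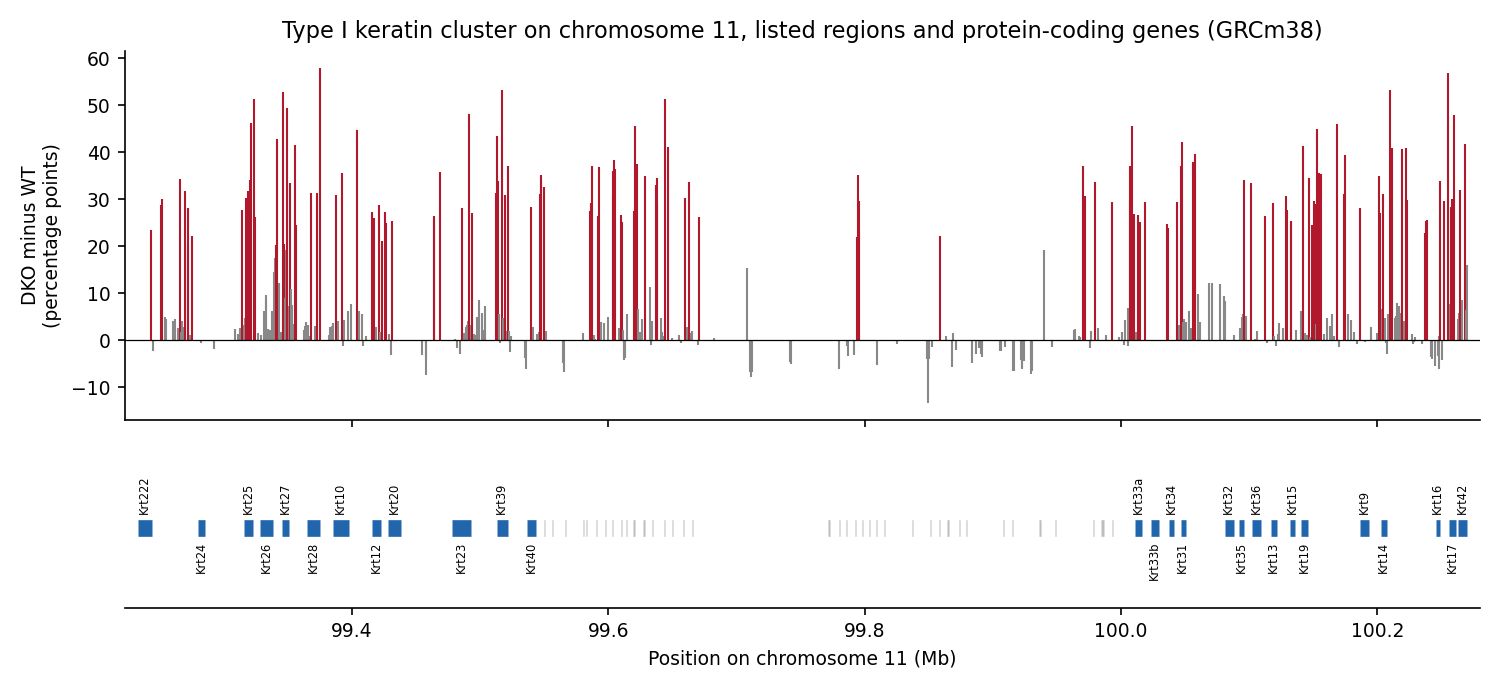
Difference in methylation, DKO minus WT in percentage points (vertical axis, each line a listed region, red where at least 20 points higher), along the type I keratin cluster of chromosome 11 in Mb (GRCm38), with keratin genes in blue and other protein-coding genes in grey. Of the 409 listed regions, 140 are at least 20 points higher and 1 is at least 10 points lower.

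Transcription factors of the hair matrix formed the list with the next highest coverage, a mean of 8.67% over 25 genes (95% range of shifted lists 1.38 to 4.27, circular-shift permutation test, adjusted p = 0.0008), and 19 of the 25 lay above the mean of all genes. Coverage was 21.9% for Dlx3, 21.1% for Ovol1, 20.4% for Klf4 and 17.9% for Vdr, the vitamin D receptor, which is needed for hair cycling. At Bcl11b, a zinc finger factor of epithelial and T cell differentiation, a region inside the gene (chromosome 12, 107934641 to 107935446) was at 18.8% in the WT and 79.2% in the DKO per the authors' deposited table (60.4 points, spread estimate 4.30). At Prdm1, a transcriptional repressor that is also on the dermal papilla list, a region inside the gene (chromosome 10, 44446649 to 44447857) was at 24.0% and 82.3% in the authors' deposited table (58.3 points, spread estimate 4.65).

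Signalling pathways of hair follicle growth also lay above the mean of all genes, by smaller factors. By the same permutation test, mean coverage was 5.72% for 31 BMP and TGF-beta genes and 5.25% for 35 Wnt genes (adjusted p = 0.0008 each), 4.78% for 27 FGF, EGF and Eda genes (adjusted p = 0.0224), 5.34% for 13 Shh genes (adjusted p = 0.0392) and 4.62% for 25 Notch genes (adjusted p = 0.0362). Id3 at 21.0008% and Bmp4 at 20.3% led the BMP list, Fzd1 at 17.9% the Wnt list and Jag2 at 17.0% the Notch list. Within Axin2, a target and inhibitor of Wnt signalling, a region of 60 positions went from 24.8% in the WT to 82.6% in the DKO in the authors' deposited table, and within Bmpr2 a region of 25 positions went from 22.6% to 82.5% in the authors' deposited table. Regions across an end of Jag1 (21.7% and 80.5%) and inside Edar (22.4% and 76.7%) differed by similar amounts in the authors' deposited table. The 15 genes of follicle stem cells and the outer root sheath had a mean of 5.34% (permutation test, adjusted p = 0.0362), with Lgr5 and Lgr6 holding the widest gains. The cell cycle list (mean 4.73%, adjusted p = 0.0295) and the list of DNA methylation and demethylation genes (4.86%, adjusted p = 0.0252) passed the permutation test as well. With the window reduced to the gene body, 5 of the 12 lists that lay above the genome still passed, namely both keratin lists, the hair matrix factors, the Wnt list and the cell cycle list. On autosomes alone the stem cell, Notch, Shh and cell cycle lists no longer passed. The cell cycle list also fell out at 30 points (permutation test, adjusted p = 0.236) and as a percent of positions (adjusted p = 0.455). The Notch list did so by the permutation test as a percent of positions (adjusted p = 0.139) and against length-matched lists (adjusted p = 0.0510). The stem cell list fell out at 30 points (permutation test, adjusted p = 0.0917). The Shh list fell out with at least 10 positions per region (permutation test, adjusted p = 0.0680).

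**Figure D3:**
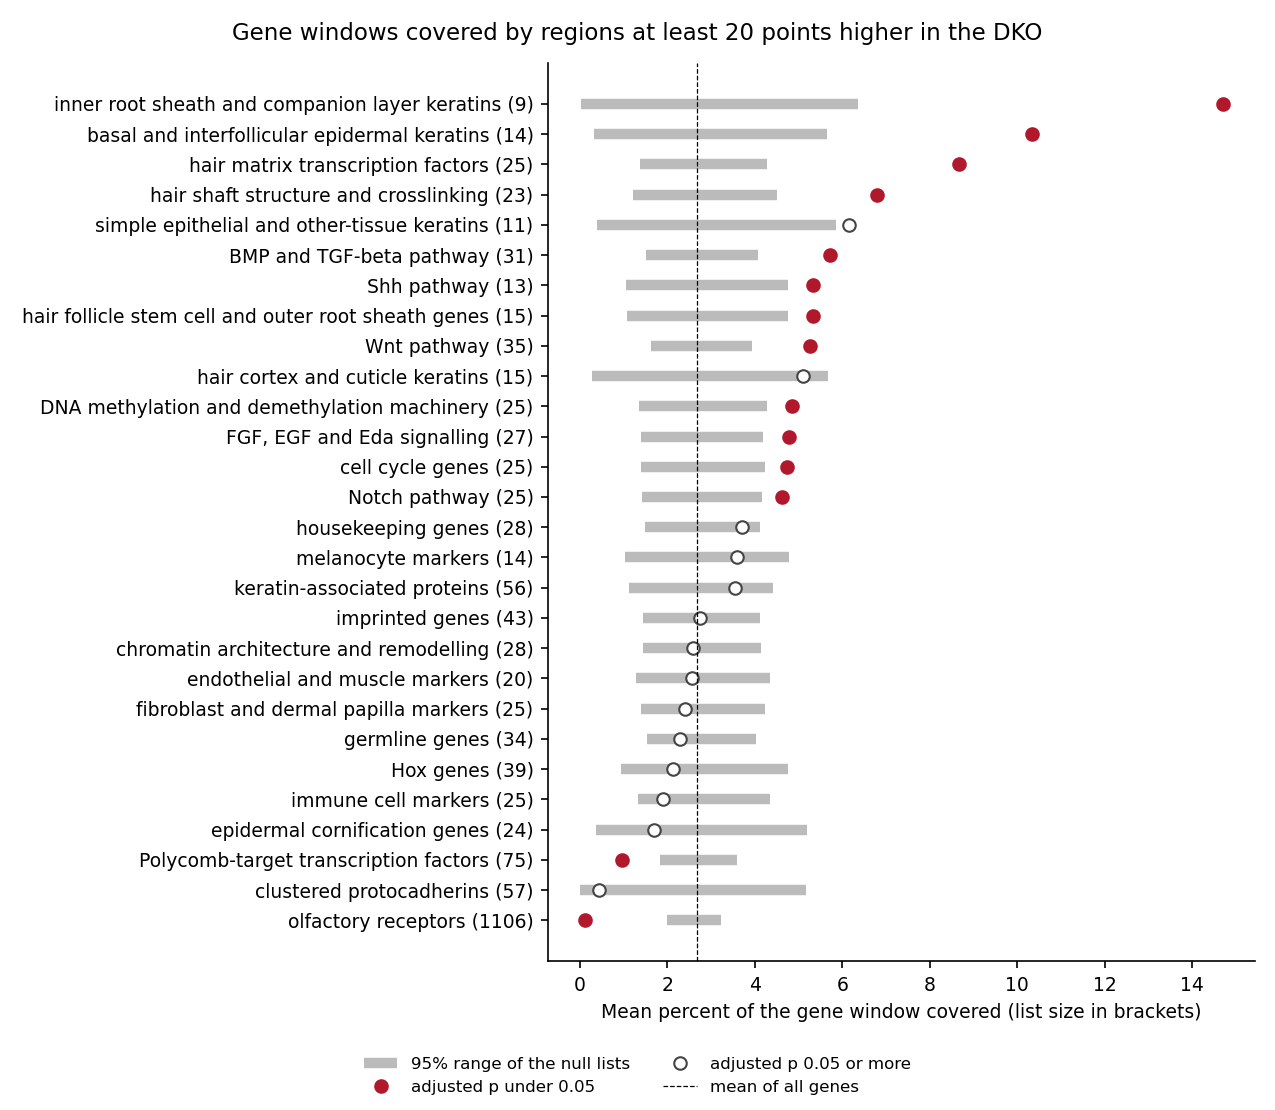
Mean percent of the gene window covered by regions at least 20 points higher in the DKO (horizontal axis) for the 28 gene lists, as points filled where the adjusted p was under 0.05, with grey bars for the 95% range of shifted lists and a dashed line at the mean of all genes, 2.67%. Inner root sheath keratins lie farthest to the right at 14.7%, and olfactory receptors farthest to the left at 0.107%.

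None of the remaining lists lay above the genome mean past the threshold. Olfactory receptors, a large family of odour receptor genes, had a mean of 0.107% over 1106 genes, and developmental transcription factors known as Polycomb targets had a mean of 0.959% over 75 genes (circular-shift permutation test, adjusted p = 0.0008 each). Clustered protocadherins were at 0.433%, but neighbouring members share regions and the permutation test did not pass (adjusted p = 0.266). Against length-matched lists, which do not keep neighbours together, 3 lists lay below the genome mean past the threshold, in place of 2. Hox genes (2.12%), germline genes (2.28%), imprinted genes (2.75%), chromatin architecture and remodelling genes (2.59%) and housekeeping genes (3.71%) did not pass the permutation test either, with adjusted p from 0.230 to 0.965. The markers of other skin cells were at 2.40% for fibroblasts and dermal papilla, 3.58% for melanocytes, 1.90% for immune cells and 2.55% for endothelium and muscle (permutation test, adjusted p from 0.440 to 0.965). Single regions beside such markers still rose, as inside Mitf (29.6% in the WT, 80.5% in the DKO), Dct (29.3% and 82.3%) and Pecam1 (24.3% and 75.1%) in the authors' deposited table.

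Near gene ends, more keratin, stem cell, hair shaft and hair matrix genes than expected held a listed region higher in the DKO by any amount. A listed region higher in the DKO lay within 1 kb of an end in 8 of 9 inner root sheath keratins (3.70 expected from random lists matched on gene length, permutation test, adjusted p = 0.0297), 11 of 14 basal keratins (5.65 expected, adjusted p = 0.0259) and 13 of 15 stem cell and outer root sheath genes (6.61 expected, adjusted p = 0.00896). The counts were 18 of 25 for hair matrix transcription factors (10.9 expected) and 17 of 23 for hair shaft structure (10.04 expected), with an adjusted p of 0.0259 each. By the permutation test, fewer genes than expected held such a region among the Polycomb-target factors (7 of 75, 30.9 expected), the clustered protocadherins (0 of 57, 24.4 expected) and the olfactory receptors (17 of 1106, 167.5 expected), each with an adjusted p of 0.00187, and among the imprinted genes (10 of 43, 18.8 expected, adjusted p = 0.028). Keratin-associated proteins also passed the permutation test (19 of 56, 6.97 expected, adjusted p = 0.0028), but their length-matched pool holds many olfactory receptors, and with circular shifts they lay on the other side without passing (adjusted p = 0.725). Matched on the number of listed regions per gene, no list held more such genes than expected past the threshold, so these counts do not separate the direction of change from the number of regions listed. With circular shifts the keratin lists no longer passed. Those that still passed with more genes were the stem cell, hair matrix factor and hair shaft lists. With circular shifts 2 lists held fewer genes than expected past the threshold, in place of 4. Lists matched on gene length do not keep neighbouring genes together, and protocadherin genes can share a gene end, as Pcdhga1 and Pcdhga10 do.

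**Figure D4:**
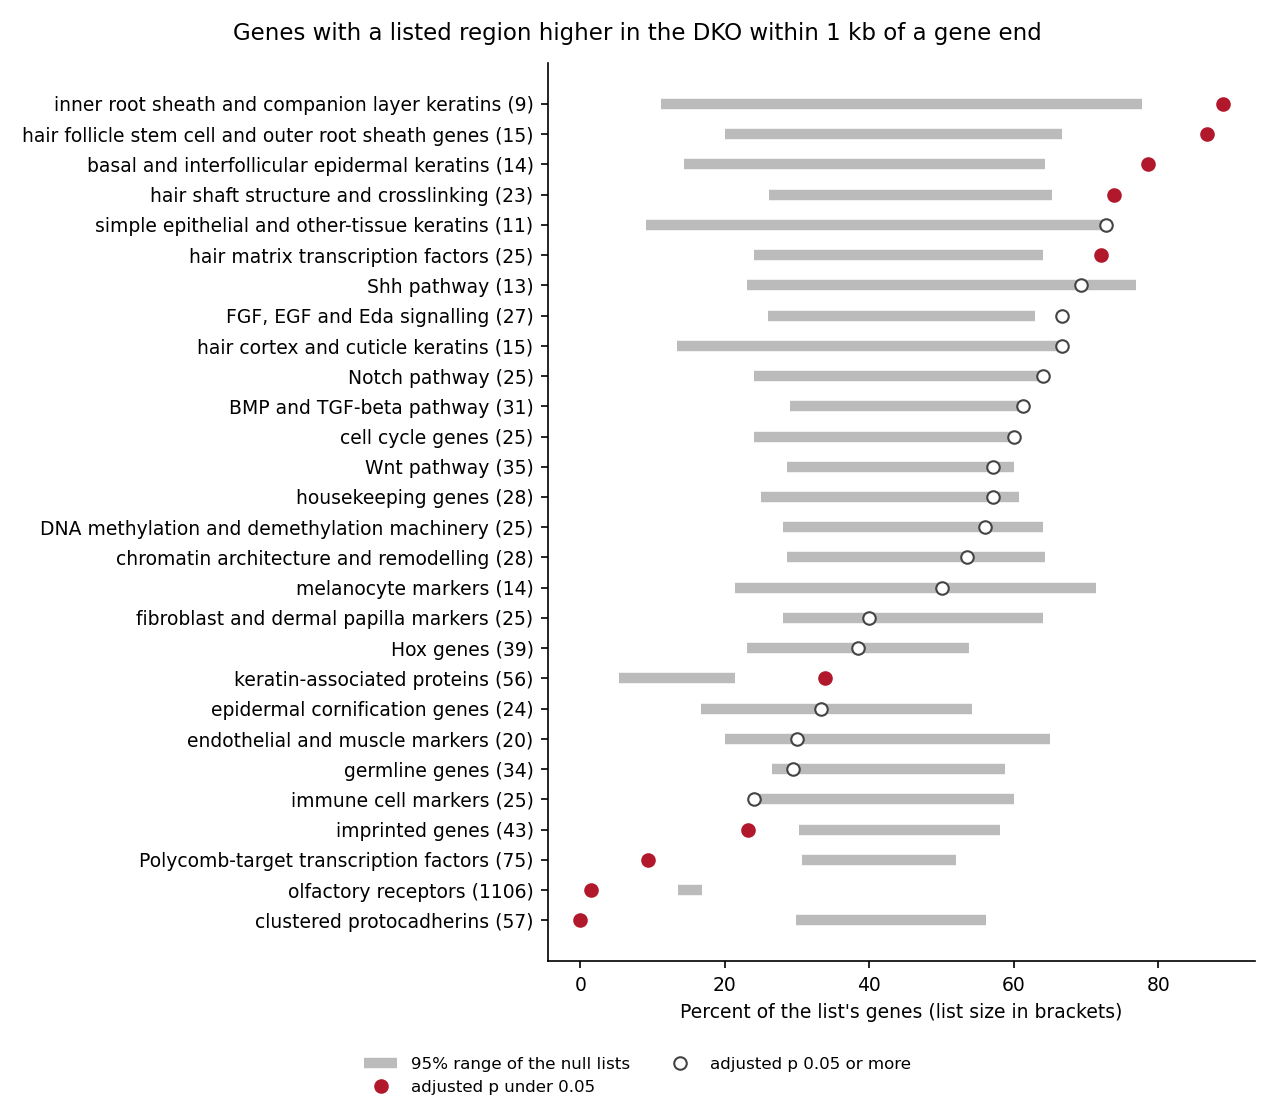
Percent of the genes of each list with a listed region higher in the DKO within 1 kb of a gene end (horizontal axis), as points filled where the adjusted p was under 0.05, with grey bars for the 95% range of random lists matched on gene length. Inner root sheath keratins are at 88.9% and clustered protocadherins at 0%. The random lists do not keep neighbouring genes together, and protocadherin genes can share a gene end.

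Over the whole gene and 5 kb on either side, most genes held listed regions of either direction, and presence alone separated few lists. A region higher in the DKO by any amount lay in the windows of 15585 of 21911 genes, and 6 of the 28 lists differed from length-matched random lists. All 23 hair shaft structure genes (17.8 expected, permutation test, adjusted p = 0.0123), 26 of 28 housekeeping genes (19.205 expected, adjusted p = 0.0224) and 27 of 56 keratin-associated proteins (12.2 expected, adjusted p = 0.00187) held 1, while Polycomb-target factors (25 of 75), clustered protocadherins (35 of 57) and olfactory receptors (55 of 1106) held fewer than expected. The keratin-associated proteins turned to the other side with an unmatched Fisher's exact test (adjusted p = 0.00296). With circular shifts 2 lists held fewer genes than expected past the threshold, in place of 3. Matched on the number of listed regions per gene, no list held more genes than expected past the threshold.

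Losses were mostly small, and few genes held a large one. A region lower in the DKO by any amount lay in 18113 gene windows, but only 1861 windows held a region at least 10 points lower, and 87 windows 1 at least 20 points lower. By any amount, hair matrix transcription factors held fewer than expected (16 of 25, 21.8 expected, permutation test, adjusted p = 0.021), as did olfactory receptors (403 of 1106, adjusted p = 0.0056), while housekeeping genes (28 of 28) and clustered protocadherins (56 of 57) held more (adjusted p = 0.021 each). Of these calls only that of the olfactory receptors was kept with circular shifts and with gene bodies. It turned to the other side when matched on the number of listed regions. With at least 10 points no list passed, and none of the genes of the 4 keratin lists (15, 9, 14 and 11 measured genes) held such a region. Of the 84 markers of other skin cells, 5 held a region at least 10 points lower (8.09 expected).

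The widest gains inside genes, among regions of at least 10 positions, were at Casz1, Arel1, Camk2g, Lrrc15, Rasgef1b and Ptgfrn. In Casz1, a zinc finger transcription factor gene, the 72 positions at chromosome 4, 148873822 to 148874881, were at 17.9% in the WT and 93.1% in the DKO per the authors' deposited table (75.1 points, spread estimate 3.51). In Arel1, at chromosome 12, 84941667 to 84942060, the level was 16.0% and 89.2% in the authors' deposited table (73.1 points, spread estimate 3.97), and in Camk2g, a calmodulin-dependent kinase gene, at chromosome 14, 20757109 to 20758019, it was 17.0% and 88.5% in the authors' deposited table (71.5 points, spread estimate 3.46). The regions in Lrrc15, Rasgef1b and Ptgfrn rose by 67.1, 66.4 and 65.7 points in the authors' deposited table. The widest losses were smaller. A region across an end of Rtl8c on the X chromosome went from 37.7% to 11.8% in the authors' deposited table (fell by 25.9 points, spread estimate 5.08), and Alpk1 on chromosome 3 from 50.2% to 25.4% (fell by 24.8 points, spread estimate 4.596). Ank2 fell by 24.3 points, Gabrg3 by 22.5, Il7r by 21.9 and Enox2 by 21.1 in the authors' deposited table. The regions of Alpk1, Ank2, Gabrg3 and Il7r held 19, 12, 12 and 10 positions. With at least 20 positions, nearer to the planned 10 CpGs, these 4 genes were not named, while Rtl8c, Enox2 and the 6 gains were. The regions in Alpk1 (127700364 to 127700840) and Ank2 (127106224 to 127106781) lie on chromosome 3, as does the deleted Tet2 (133463677 to 133545136). Whether their losses are linked to the altered Tet2 locus was not tested. Rtl8c and Enox2 lie on the X chromosome, where 19.5% of the regions that differed by at least 10 points were higher in the DKO, against 92.6% on the autosomes, and a difference in the sex of the animals was not ruled out. At 20 points or more, 455 X regions were higher and 66 lower, so these losses are not typical of wide X differences.

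The deleted genes themselves held gains of at least 20 points, as did 64.4% of all 21911 genes. Such gains covered 3.15% of the Tet2 window, 8.22% of the Tet3 window and 2.56% of the Tet1 window. The mean over all genes was 2.67%. The Tet2 window (chromosome 3, gene at 133463677 to 133545136) held 29 listed regions, of which 24 were higher in the DKO and 10 by at least 20 points. The Tet3 window (chromosome 6, 83362373 to 83457208) held 43, of which 38 were higher and 13 by at least 20 points. The widest difference at Tet3 was inside the gene at 83439028 to 83439853, 10.7% in the WT and 61.9% in the DKO per the authors' deposited table (51.2 points, spread estimate 3.797). At Tet2 it was 3913 bp outside the gene, at 133549049 to 133549241, with 33.8% and 71.0% in the authors' deposited table (37.2 points, spread estimate 3.60). The dense regions at 1 end of each gene, with 249 and 254 positions, were near 3% in both genotypes, at 3.03% and 2.83% for Tet2 and 3.04% and 2.94% for Tet3 in the authors' deposited table. Tet1, which was not deleted, held 21 listed regions, 3 of them at least 20 points higher, the widest inside the gene at chromosome 10, 62847037 to 62847851 (26.6% and 72.6% in the authors' deposited table). At Krt14, whose promoter drives the Cre recombinase, 5 of 11 listed regions rose by at least 20 points, the widest 2071 bp outside the gene at chromosome 11, 100209581 to 100210879, from 20.2% to 73.4% in the authors' deposited table (53.1 points, spread estimate 4.05). Methylation does not show whether an exon is deleted, so these values check no label.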

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

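The tests of the offset in the next paragraph were chosen after the result was seen, except that the outcome of the test on single positions was set down before it was run.

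In 110784 regions the authors' statistic and the difference of means, taken as WT minus DKO, had opposite signs. The statistic was positive although the DKO mean was higher. The report uses the means and not the statistic, so these regions stand out as a signal in a column that its comparisons leave aside. Averaging over unlike positions within a region is argued against by single positions, since 3615 of the 25114 regions of 1 position also had opposite signs. A single offset over the whole genome is argued against by the correlation of the offset between regions within 5 kb of each other, with a Pearson r of 0.98 across regions, which are not independent replicates. A local offset is consistent with that value together with the r of 0.115 between regions over 1 Mb apart, and may come from a correction of the statistic for a local background, with the biological part of that background not tested.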

How the results depend on the processing

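Alternatives with a minimum of 20 positions or 2 spreads, with 30 or 50 points, with 2 limits at once, with lists matched on listed regions, and all alternatives of window coverage were chosen after the data were seen.

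The number of regions, 484555 in the table, was 138508 at a difference of at least 10 points, 111462 at 20, 46690 at 30 and 1675 at 50, 313641 with at least 5 positions, 213563 with 10, 96389 with 20, 273084 at 200 bp or more, and 158310 at 2 spreads or more. On autosomes alone it was 135728 at 10 points and 110851 at 20, and at 20 points it was 63015 with 10 positions and 30783 with 20. The share higher in the DKO, 48.2% over all listed regions, turned to a majority in these settings. At the limits in points small differences of both signs drop out, and most losses were small. At 10 points 12321 of 251195 losses and 126187 of 233360 gains remained. Elsewhere the cause was not tested. The share was 91.1% at 10 points, 99.6% at 20, 99.93% at 30, 99.88% at 50, 53.1% with 5 positions, 56.9% with 10, 61.6% with 20, 52.4% at 200 bp and 82.3% at 2 spreads. On autosomes alone it was 48.9%, with 92.6% at 10 points and 99.74% at 20, and at 20 points 99.96% with 10 positions and 99.97% with 20. The gap between the medians inside and between genes, 2.01 points, was 2.10 with gene ends of 5 kb, 1.33 with 5 positions, 1.4955 at 10 points and 1.92 on autosomes.

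The number of lists past the threshold moved as follows, and the cause was not tested. For higher regions, 6 became 10 with Fisher's exact test and 3 with lists matched on listed regions. For lower regions, 4 became 2 with circular shifts, 8 with Fisher's exact test, 2 with gene bodies, 0 at 10 and 0 at 20 points, and 10 matched on listed regions. Near gene ends, 10 became 5 with circular shifts and 2 matched on listed regions. For window coverage, 14 became 8 with gene bodies, and 10 on autosomes alone, where the stem cell, Notch, Shh and cell cycle lists dropped out. Keratin-associated proteins turned to the other side with circular shifts and Fisher's exact test, at the same 27 genes with a higher region and 19 near gene ends. Among lower regions, olfactory receptors turned at 10 points (66 genes) and matched on listed regions (403 genes), housekeeping genes at 10 and 20 points (0 genes), and protocadherins at 20 points (0 genes). Only 87 of 21911 genes held a region at least 20 points lower, so a count of 0 at that limit was likely beforehand and carries no information. For single lists in these settings, 194 results with higher regions stayed the same, 18 became stronger and 10 weaker, with 189, 16 and 14 for lower regions, 187, 8 and 27 near gene ends, and 172, 7 and 17 for window coverage. Of the 67 named genes, 59 were named again with at least 5 positions, and of the 12 with the largest differences 8 were named again with 20 positions.

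No paired analysis was possible because the table gives group means with no column per library, and for the same reason leaving out each library, coverage minimums and Fisher's exact test on reads were not run. A stricter adjusted p of 0.01 for regions was not run, since the table has no p-values. Depth is unknown, so it limits these values to an extent that could not be measured here.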

Other observations

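The values and tests in this part, the window coverage included, were chosen after the data were seen, except that the outcomes of the tests on Xist, on cytosine positions and on gene length were set down before those tests were run.

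The keratin clusters and the epidermal differentiation complex, both dense arrays of epidermal structural genes, were covered to unlike extents, and no test compared them. Between Krt222 and Krt42 on chromosome 11 (type I keratins), regions at least 20 points higher in the DKO covered 6.79% of 1037 kb, with 135 such regions per Mb. Between Krt80 and Krt18 on chromosome 15 (type II keratins) they covered 5.63% of 684 kb. Over all autosomes the coverage was 1.97%, with 44.9 regions per Mb, and 168 of 22994 autosomal windows as long as the type I cluster, and 1601 of 34974 as long as the type II cluster, were covered as much. In the epidermal differentiation complex on chromosome 3, between Sprr2a1 and Tchhl1, where the cornified envelope genes lie, the coverage was 1.43%, at the 44.2 percentile of windows of that length.

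Among windows of at least 20 kb, coverage by gains of 20 points was high at Klf5 (24.4%), an epithelial transcription factor. Lbh (22.2%), Hopx (20.5%), a marker of hair follicle stem cells, and Etv3 (20.1%) were also among the 15 highest, together with Krt72 and Ovol1.

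Windows of 12 lists, 5 of keratin and hair follicle genes and 7 of signalling, cell cycle and DNA methylation genes, held more gains than the genome, and technical explanations were weighed. When coverage was measured in cytosine positions, 10 of the 12 lists still passed, so the unit of coverage is not the whole cause. Both units use the same listed regions, so this cannot show whether windows dense in positions are listed more readily. Gene length is argued against as the whole cause, since 11 passed against length-matched lists. Those lists do not keep neighbouring genes together, so this is weaker for the keratins, which lie in clusters. A local offset that eased listing would have to be lower in these windows, and its median was higher, 2.19 against 1.41 for all genes, but the offset rises with coverage itself (Spearman 0.597 over 19421 genes), so this is not counted as excluding it. Cells of other types in the DKO sort would bring losses at their own marker genes, and 5 of 84 such markers held a region at least 10 points lower, against 8.09 expected (binomial SD 2.70), so this stays open too. A different mix of follicle cell layers and an effect of the genotype on these genes were not tested.

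X regions were lower in the DKO, with a median difference of -6.38 points over 9306 regions, although 455 rose and 66 fell by at least 20 points. Island-like X regions had medians of 20.4% and 10.7% and a median difference of -9.22 points, with 205 of 210 lower. Autosomal ones listed under the same positive bound had a median difference of 0.0748 points. But island-like autosomal regions had a WT median of only 3.09%, so a median fall of that size was not possible there. They therefore do not decide whether selection on the statistic lowered the X regions. The mean of a group with more female cells would hold more methylated islands of the inactive X, so a difference in sex between the libraries is a candidate explanation. The region nearest to Xist, 326 bp from the gene, was 29.95 points higher in the DKO (31.9% and 61.8% in the authors' deposited table), as that explanation needs, but 85.0% of the listed regions (listed for their difference) with a WT level of 20% to 40% also rose by at least 20 points, and 1 of the 3 regions around Xist was lower. It stays open whether the loss in the other X regions, -6.32 points over 9096 regions, has the same source, and the sex of the animals was not given in the labels used here.

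On the Y chromosome 433 of 438 regions were lower in the DKO, with a median difference of -14.4 points. On the autosomes, the share of higher regions among those that differed by at least 10 points ran from 86.5% on chromosome 3 to 97.5% on chromosome 11. Chromosome 3, which carries the deleted Tet2, held 1098 regions at least 10 points lower, the most of any autosome. Chromosome 6, which carries the deleted Tet3, held 535, and 92.9% of its regions that differed by at least 10 points were higher. Ranked by the summed statistic, 740 of the 1000 leading regions differed by less than 5 points, and the leading region, on chromosome 5 at 136564986 to 136569413 with 644 positions, was at 2.77% in the WT and 3.72% in the DKO in the authors' deposited table.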
